A study of Mus musculus with 10 samples.

How the data were processed

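RNA from 10 libraries of sorted mouse LTi-like cells, 60 cells each, was amplified with Smart-Seq2, sheared, and sequenced as Illumina libraries, per the labels' protocols. The samples formed 5 groups of 2, taken from the titles and genotype labels: WT gut, KO gut, WT mLN, KO mLN and WT spleen. The values used are the FPKM deposited by the authors in 1 table of 21938 genes and 10 libraries, per the file headers. The submitters' processing notes name Bowtie2, RSEM and the genome builds mm10 and GRCm38. The versions, the gene annotation, the strand setting and whether pairs or single reads were counted are not given in the sources used here.

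The table had 1 empty line, which was dropped, 23 gene symbols that a spreadsheet had stored as dates, which were restored through their gene identifiers, and 22 symbols shared by several genes. Of the identifiers 21862 matched GENCODE mouse release 21, built on GRCm38, from which symbols, positions and biotypes were taken. 971 genes were listed at 0 in every library. Low FPKM values fell on multiples of what 1 read is worth. With union exon lengths from that annotation, 19510 of 21886 genes (89.1%) and 86.9% of values came out whole within 0.01 reads. For 2421 genes the length was solved from the values themselves. The recovered denominators were 9887767 and 10323588 reads in WT gut, 9477544 and 8238851 in KO gut, 7046520 and 10714455 in WT mLN, 10271996 and 10821211 in KO mLN, and 11339342 and 11023368 in WT spleen. A floor of 3 reads per library, averaged over a group, was used for folds against a group at 0. Such floors cover counting error only, since PCR copies of reads are not independent molecules. Gapdh, a housekeeping gene with many pseudogenes, was low (3.63 to 13.4 FPKM against 265 to 978 for Actb). Its length in use, 4133 bases against 2679 for Actb, also lowers its FPKM. Reads were recovered as whole numbers for 100.0% of values, so it is open whether the named RSEM step made this table. How reads shared between near-identical copies were counted is therefore not known, and ribosomal protein genes, haemoglobins and Gapdh are uncertain. Reads of overlapping genes are uncertain as well, which among the genes named covers Trdj1, Trdj2, Trdd2, Trdc, Rorc, Rora, Tcf7, Gata3, Cxcr5, Cxcr6, Cd27, Cd74, Colq, Crem, Csf1r, Fas, Gapdh, Gm23935, Gpr183, H2-Oa, Hif1a, Hk2, Igfbp7, Bcl2a1d, Litaf, Ltb, Osgin2, Piwil4, Ramp3 and Zfp36.

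Replicates of a group correlated at 0.837 (WT gut), 0.782 (KO gut), 0.769 (WT mLN), 0.835 (KO mLN) and 0.897 (WT spleen), while libraries of different groups correlated at 0.662 to 0.88, so most replicates were no more alike than some libraries of different groups. Replicates differed by far more than counting noise (chi-square over degrees of freedom 61.5 to 171 across 2883 expressed genes). No pair was a duplicate, and each library counted as 1 replicate.

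FPKM is not a count, so tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. 1 model held the 5 groups and all 10 libraries, which left 5 residual degrees of freedom, and used empirical Bayes moderation with an intensity trend. The 12977 genes with at least 1 FPKM in at least 2 libraries were tested. P-values were two-sided and Benjamini-Hochberg adjusted within each comparison, with a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot go below 0.333, so none was used. Gene lists were tested with camera, which asks whether a list moved relative to all other genes, at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes moved on balance in 1 direction. With an estimated correlation camera also rests on the 5 residual degrees of freedom, so a call lost there need not reflect correlated genes. Of 29 lists 26 had at least 5 measured genes and were tested, and p-values were adjusted over the lists within a comparison. The groups, tests, lists, rule for named genes and most alternatives were set before the data were examined.

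The genes named were, per comparison, the 10 largest changes in each direction past the threshold with no overlap between the libraries of both groups and a mean of at least 10 FPKM in the higher group, leaving out predicted, clone and pseudogene symbols. Where fewer than 5 passed in a direction, the 5 with the smallest p were taken as values. For 2 libraries against 2, chance alone separates the groups in 33.3% of genes. Up to 4 members past the threshold were added from each list, or up to 2 as values where none passed, together with fixed genes: Id1, Id2, Id3, the sort gate genes, Il22, Il17a, Il17f, Lta, Ltb, Tnfsf11, Ccr6, Cxcr5, Kit, Ncr1, Tbx21, Gata3, Tcf7 and Cd3e. Not every gene that met the rule is described. Gm13840, Trac, Trdc and markers of single libraries, and the remaining genes that were called in both KO comparisons or are named from within a list, were named from the results.

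Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, median-of-ratios scaling, columns rescaled to equal sums, quantile normalization, only the libraries compared, moderation without a trend or robust, library weights (arrayWeights), the replicate number as a block, a log2 change of at least 1, and leaving out each library in turn. Added after seeing the data were limma's voom on the recovered reads, a fit without the 2 libraries richest in Gm23935, a fit without both KO libraries numbered 1, and protein-coding genes only. Overlaps of calls were set against the overlap of independent lists, and for WT gut against WT mLN with WT gut against WT spleen, which share WT gut, against the correlation and covariance in 20 simulations of unchanged groups. Other pairs that share libraries were not simulated.

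The test was checked on simulated data shaped like the comparison of KO with WT gut over 12977 genes, with 40 genes changed at each fold. It recovered 0% at 2-fold, 32.5% at 4-fold, 67.5% at 8-fold, and 97.5% at 16-fold and at 32-fold, with 4 false among 122 calls. The simulated noise was Gaussian and independent between genes, and changes were planted only in better expressed genes. The real test may therefore do less well. The median standard error of a log2 change was 0.69, and 0.97 for the interaction. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. Isoforms, splice junctions over the floxed exons and reads outside annotated genes were not analysed here.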

Results

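The transcriptomes of mouse lymphoid tissue inducer (LTi)-like cells, the CD4-bearing innate lymphoid cells that depend on the transcription factor RORγt, were compared between tissues and between genotypes. Each library was made with Smart-Seq2, a full-length cDNA method for very small inputs, from 60 cells sorted from C57BL/6 mice as viable, lineage-negative, CD45+, CD90+, CD127+, CD4+ and Rorc+. The 10 libraries formed 5 groups of 2. Cells with floxed but intact Id2 (Id2fl/fl, here WT) came from gut, mesenteric lymph node (mLN) and spleen, and cells from mice that also carried the Rorc-cre transgene (here KO) came from gut and mLN. Expression was read as FPKM, fragments per kilobase of transcript scaled to the reads of the library. The low values fell on the steps of whole reads, which gave a denominator of 7046520 reads in the shallowest library (WT mLN 1) and 11339342 in the deepest (WT spleen 1), a ratio of 1.61. Between 8650 and 10767 genes reached 1 FPKM per library. Values below are means ± SD over the 2 libraries of a group (n = 2), and log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels do not say whether the libraries of a group came from separate animals. The p-values of single genes therefore rest only on the spread between libraries within groups, pooled over all 5 groups, which may be technical. Those of camera at its preset correlation rest mainly on the spread over genes and do not measure the spread between libraries.

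Id2, the HLH protein that sequesters E proteins and is the target of the deletion, was low in every KO library and high in every WT library. It stood at 396 ± 129 FPKM in WT gut and 3.89 ± 5.08 in KO gut, and at 598 ± 19 in WT mLN and 5.18 ± 3.79 in KO mLN. WT spleen cells held 509.7 ± 52.8. The log2 change was -6.86 (SE 0.78, limma adjusted p = 0.00711) in gut and -6.75 (adjusted p = 0.0103) in mLN. The gene lies at chromosome 12, positions 25093799 to 25097140 on the minus strand (GRCm38), and the labels do not say which exons are floxed, so reads outside the deleted part can remain. In gut the adjusted p rose to 0.0579 without WT gut 1 and to 0.0747 without WT gut 2, and in mLN to 0.0862 without WT mLN 1, 0.0622 without KO mLN 1 and 0.0746 without KO mLN 2. With voom on the recovered reads the gut value was 0.0508.

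**Figure D1:**
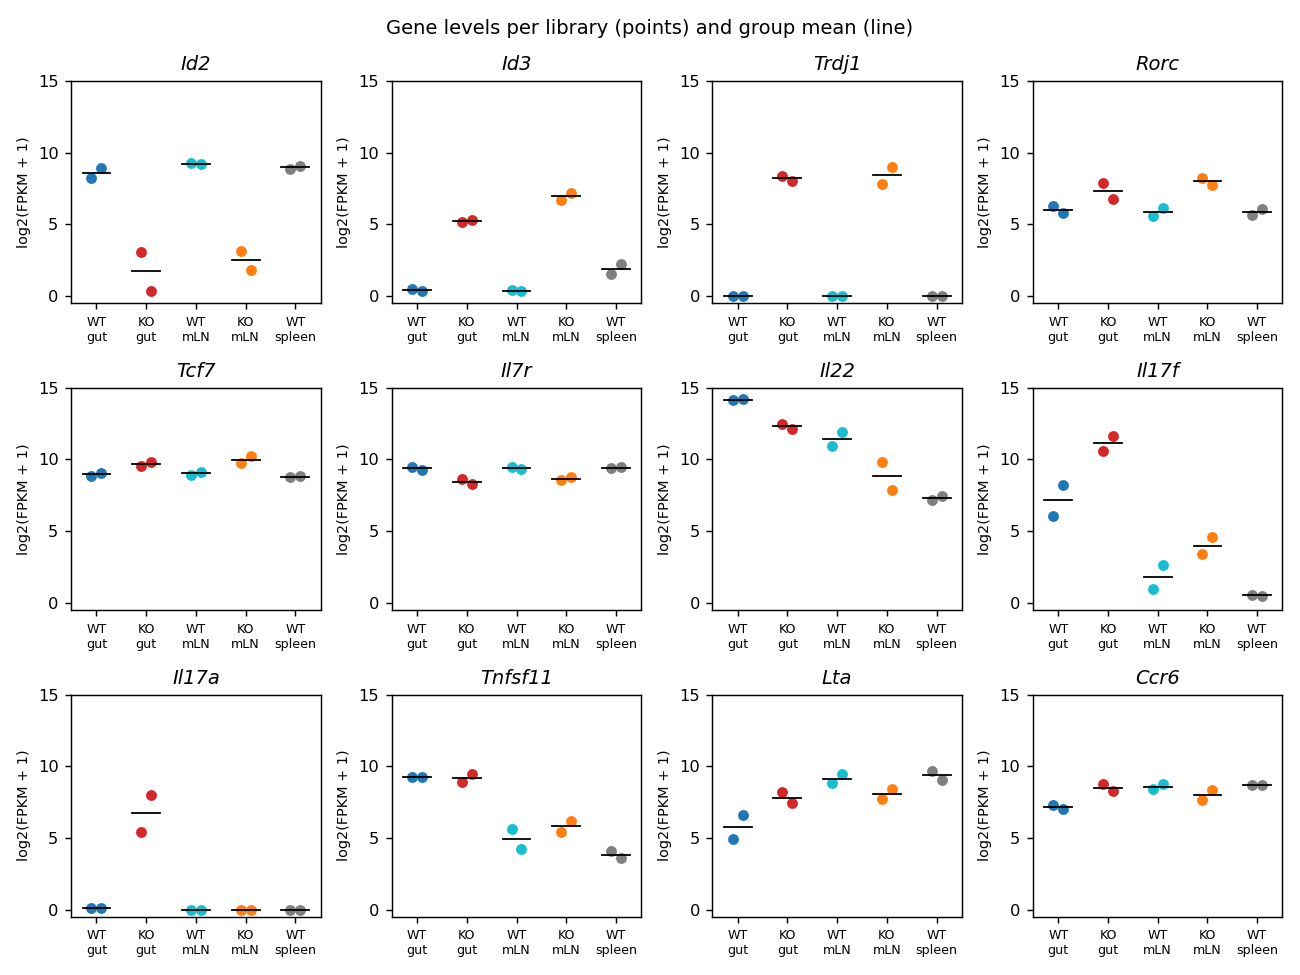
Expression of 12 genes as log2(FPKM + 1) on the vertical axis, with 1 point per library, the 5 groups along the horizontal axis and a black line at each group's mean. Id2 averaged 396 and 598 FPKM in WT gut and WT mLN against 3.89 and 5.18 in KO gut and KO mLN, while Id3 averaged 0.333 and 0.289 against 36.8 and 124.

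The comparison of KO with WT gut cells asked how intestinal LTi-like cells with deleted Id2 differed. No group carried Rorc-cre with intact Id2, so Id2 loss and the transgene cannot be told apart, here or in mLN. Id3, a paralog that also binds E proteins, rose from 0.333 ± 0.0883 to 36.8 ± 2.83 FPKM (log2 change 4.82, adjusted p = 0.005). The T cell receptor delta joining segments Trdj1 and Trdj2 were at 0 in WT gut and rose to 296 ± 44.3 and 139.9 ± 23.3, at least 50.7-fold and 27.8-fold over the floor of 3 reads per library. Il17a, an inflammatory cytokine, rose from 0.0845 ± 0.00258 to 151 ± 154 (adjusted p = 0.00836), with 41.99 in KO gut 1 and 259.65 in KO gut 2. The call was lost without WT gut 1 (0.0744) or WT gut 2 (0.0747), with voom (0.0846) and with only the libraries compared (0.319). The neutrophil chemokine Cxcl1 fell from 139.8 ± 103 to 0.0886 ± 0.0338, and Fasl, the ligand of the death receptor Fas, from 34.9 ± 3.16 to 0, at least 199-fold lower.

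Other large increases in KO gut were those of Acod1, the enzyme that makes itaconate (0.732 ± 0.983 to 165 ± 9.94 FPKM), and of Ly6a, which encodes the surface protein Sca-1 (0.542 ± 0.539 to 61.4 ± 35.9). So were those of Ighm, the immunoglobulin mu constant region (9.74 ± 11.4 to 289 ± 148), and of Nsg2, a vesicle protein of neurons (0.0593 ± 0.015 to 50.4 ± 31.7). Sult5a1, a sulfotransferase, went from 0 to 45.7 ± 11.9, at least 681-fold. Olfr523, annotated as an olfactory receptor, went from 0.0459 ± 0.0014 to 107 ± 8.63, but it lies in the region of chromosome 7 that holds the related scavenger receptor genes Cd163l1 and 5830411N06Rik, so its reads are uncertain. Sell, the L-selectin used in lymph node entry, rose to 13.3 ± 0.0344 from 0.0253 ± 0.0126. Decreases included Dkk3, a secreted Dickkopf family protein (44.6 ± 13.4 to 0.0495 ± 0.0189), the pseudophosphatase Styx (54 ± 19 to 0.404 ± 0.316), the forkhead factor Foxs1 (63.1 ± 27 to 0.173 ± 0.0171), and Ptges, a prostaglandin E synthase (92.4 ± 17.6 to 1.89 ± 2.52). Slc41a3, Psd2, the MHC class II chaperone modifier H2-Oa, the replication licensing factor Mcm5 and the fatty acid oxidation enzyme Acadm fell as well, with adjusted p between 0.0126 and 0.0468.

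The fixed T cell list held 25 genes, of which 16 passed the filter, without Cd3d, Cd3e, Cd247 and Cd8b1 among others. Among these 16 measured genes 3 rose in KO gut, none fell and 13 did not pass, with the same counts adjusted over the list alone. These were Ctla4, an inhibitory receptor (2.6 ± 0.491 to 134 ± 10.1 FPKM), Cd28, a costimulatory receptor (0 to 20.4 ± 5.52, at least 420.1-fold), and Ccr7, a lymph node homing receptor (19 ± 0.836 to 156 ± 10.5). The list as a whole shifted upward (median log2 change 1.37, camera adjusted p = 1.17e-08), and it kept its call with an estimated correlation between genes (adjusted p = 0.0293). The CD3 chain gene Cd3e was at 0.799 ± 0.216 in KO gut and 0 in WT gut, at least 11-fold higher. Trac, the T cell receptor alpha constant region, was at 68.3 ± 19.8 in KO and 8.03 ± 11.4 in WT gut. Of 25 E protein driven early T-lineage genes 17 passed the filter, without Ptcra, Rag1 and Rag2 among others. Of these 17 genes 1, Id3, rose, none fell and 16 did not pass. Over the list alone 2 rose and 1 fell (median 0.7, camera adjusted p = 0.0132, adjusted p = 0.203 with an estimated correlation). That call was lost without WT gut 2 (0.082) or KO gut 1 (0.052), with a filter of 5 FPKM (0.0912) and without the 2 libraries richest in Gm23935 (0.0697).

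Of 14 ILC3 cytokines and effectors Il17a rose and 13 did not pass, while adjusted over the list alone 6 rose and 2 fell. Il17f stood at 2395 ± 1202 FPKM in KO and 184 ± 166 in WT gut (adjusted p = 0.0686). Lta, a subunit of lymphotoxin, was at 229.8 ± 84.1 and 62.4 ± 46.3 (0.141), and Il22, a cytokine that acts on epithelium, at 5115 ± 813 and 18425 ± 929 (0.189). Il22 shares most of its sequence with the copy Iltifb, so its value is uncertain. The list's camera adjusted p was 0.0158 (median 0.99), and adjusted p = 0.203 with an estimated correlation. Voom gave 0.0964, and the call was lost without KO gut 1 (0.0802), WT mLN 1 (0.0529) or WT mLN 2 (0.0549). It was also lost without both KO libraries numbered 1 (0.127), without the 2 libraries richest in Gm23935 (0.0796), with only the libraries compared (0.09) and with a filter of 5 FPKM (0.0571). The sort gate genes did not pass: Rorc, which encodes RORγt, was at 174 ± 91.5 in KO and 64.3 ± 15.6 in WT gut, Il7r (CD127) at 349.9 ± 55.1 and 668 ± 60.2, and Cd4 at 303 ± 141 and 224 ± 27.1. Tcf7, a lymphoid transcription factor outside the gate, did not pass either, at 811 ± 110 and 497 ± 44.8.

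None of 37 interferon response genes passed in KO gut, and 2 rose adjusted over the list alone, with a list median of 1.13 (camera adjusted p = 0.000335, adjusted p = 0.621 with an estimated correlation). The shift sat in KO gut 1 and the call was lost without it (0.621): Rsad2, an antiviral enzyme, averaged 181 ± 251 in KO and 0.0899 ± 0.0941 in WT gut. The 6 erythroid and platelet genes had a median of -3.29 (camera adjusted p = 0.0162, adjusted p = 0.541 with an estimated correlation), none passed and 1 fell adjusted over the list alone. Haemoglobin Hba-a1 reads lay in WT gut 1 (847.19 FPKM), and the call was lost without that library (0.636), KO gut 1 (0.0887), KO gut 2 (0.0792), WT mLN 1 (0.0529) or WT mLN 2 (0.0549). KO gut 2 also held the enterocyte gene Fabp2 (59.87 FPKM), the macrophage gene C1qa (168.88) and the CD8 chain gene Cd8b1 (13.5).

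In total 55 genes were higher and 56 lower in KO than in WT gut among 12977 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The 111 calls became 41 without WT gut 1, 42 without WT gut 2, 56 without WT spleen 1 and 55 without WT spleen 2. They were 30 without both KO libraries numbered 1 and 63 without the 2 libraries richest in the RNA gene Gm23935 (WT mLN 1 and KO gut 2). A fit of only the libraries compared called 0, here and in every comparison below. Of the 29 named genes past the threshold, 12 stayed past it without any 1 library (Trdj1, Trdj2, Acod1, Olfr523, Sult5a1, Ly6a, Cxcl1, Dkk3, Styx, Fasl, Id3 and Ctla4). The other 17 lost it without at least 1 library, with adjusted p up to 0.212 without WT gut 1 and 0.168 without WT gut 2. The calls held in 10 of 27 alternatives for Mcm5, 11 for Acadm, 12 for H2-Oa, 13 for Ptges, and 16 for Psd2 and Sell, and in 16 of 26 for Ighm. Of these 29, 19 passed with voom, 29 with median-of-ratios scaling and 27 with quantile normalization. Of 29 alternatives the call of the T cell list held in 29, interferon response in 25, E protein driven genes in 24 and ILC3 cytokines in 20, and of 28 the erythroid call in 16.

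KO and WT cells of the mLN were compared in the same way. Id3 rose from 0.289 ± 0.0399 to 124 ± 26.4 FPKM (log2 change 6.58, adjusted p = 0.00129). Trdj1 and Trdj2 were at 0 in WT mLN and at 372 ± 212 and 179.7 ± 102 in KO mLN, at least 53.7-fold and 30-fold higher, and the diversity segment Trdd2 rose from 0 to 115 ± 8.32, at least 5.23-fold. Trdd2 is 16 bases long, and its value rests on 18 and 21 reads. Trdj1 covers chromosome 14, positions 54123138 to 54123188, and Trdj2 positions 54136779 to 54136837 (GRCm38), each overlapped on the other strand by a predicted gene, so strand leaves them uncertain. Hes1, a transcriptional target of Notch, rose from 0.126 ± 0.0803 to 273 ± 23.3, and Ccr8, a chemokine receptor, fell from 159 ± 22.3 to 0.0808 ± 0.00297.

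Further increases in KO mLN were seen for Colq, the collagen tail of acetylcholinesterase (0.124 ± 0.0361 to 158 ± 17.2 FPKM), the fatty acid desaturase Fads2 (0.078 ± 0.0228 to 76.2 ± 21.2) and Ly6a (35.4 ± 13.8 to 439 ± 9.42). They were also seen for the activation and retention marker Cd69 (89.7 ± 33.6 to 496 ± 14.6) and Sult5a1 (0 to 53.2 ± 0.653, at least 666-fold). Cd163l1, a scavenger receptor with close relatives on chromosome 7, rose from 2.47 ± 3.33 to 280.1 ± 27.9. Decreases included Igfbp7, which binds insulin-like growth factors (234 ± 51.8 to 0.318 ± 0.234), the carbonic anhydrase Car2 (128 ± 50.3 to 2.45 ± 3.14), the membrane-bound chemokine Cx3cl1 (62.9 ± 13.9 to 0.854 ± 1.17), Psd2 (118 ± 35.2 to 2.41 ± 3.39), and Bcl2a1d, a survival factor with close paralogs (42.2 ± 15.9 to 0.496 ± 0.096). Cxcr6, a chemokine receptor of tissue lymphocytes, fell from 213 ± 2.63 to 69.1 ± 14.7 (adjusted p = 0.0281), and the arginase Arg1 from 82.5 ± 27.6 to 6.84 ± 5.28 (adjusted p = 0.0445). Of 27 alternatives Arg1 passed in 9, Cd163l1 in 11, Bcl2a1d in 13, Cd69 in 14, Igfbp7 and Cxcr6 in 15, Psd2 and Ly6a in 18, Car2, Cx3cl1 and Colq in 22, Sult5a1 in 23 and Fads2 in 25. Voom gave adjusted p of 0.336 for Bcl2a1d, 0.232 for Arg1, 0.172 for Car2, 0.102 for Cd163l1, 0.0982 for Cx3cl1, 0.096 for Psd2, 0.0664 for Igfbp7, 0.062 for Colq and 0.0554 for Cd69 and Cxcr6.

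Of the 16 T cell genes 2 rose in KO mLN, none fell and 14 did not pass: Cd28 (0 to 13 ± 3.16 FPKM, at least 225-fold) and the costimulatory receptor Cd27 (0.122 ± 0.172 to 74 ± 40.3). Adjusted over the list alone 7 rose (median 0.94, camera adjusted p = 9.53e-06, adjusted p = 0.0881 with an estimated correlation). Among the 17 E protein driven early T-lineage genes Id3 and Cd27 rose, 15 did not pass, and adjusted over the list alone 6 rose and 2 fell (median 0.95, camera adjusted p = 0.0438, adjusted p = 0.315 with an estimated correlation). The call was lost without WT gut 1 (0.0808), WT gut 2 (0.082), WT mLN 1 (0.0823), WT mLN 2 (0.216) or KO mLN 2 (0.0967), and with voom (0.0558). Of 21 B and plasma cell genes 11 passed the filter, without Cd19, Ms4a1 and Pax5 among others. Among these 11 Ighd, the immunoglobulin delta constant region, rose (0.221 ± 0.313 to 11.2 ± 2.71) and 10 did not pass. Adjusted over the list alone 4 rose (median 2.45, camera adjusted p = 0.00236, adjusted p = 0.175 with an estimated correlation). With protein-coding genes only, that list had an adjusted p of 0.279.

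None of 37 interferon response genes passed in KO mLN and 2 rose adjusted over the list alone (median 1.48, camera adjusted p = 4.47e-07, adjusted p = 0.548 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, averaged 188 ± 244 FPKM in KO and 1.33 ± 1.5 in WT mLN, with 360 in KO mLN 1 and 15.1 in KO mLN 2. None of 85 ribosomal protein genes passed and 7 had a log2 change above 0, around a list median of -0.55 (camera adjusted p = 5.81e-08, adjusted p = 0.548 with an estimated correlation). That call was lost without WT mLN 1 (0.0836), the library with the most Gm23935 (22310 FPKM, from 8961 reads on a length of 57 bases). Among genes that did not pass, Rorc was at 259 ± 58.4 in KO and 57.9 ± 16 in WT mLN (adjusted p = 0.0611), and Il22 at 578 ± 487 and 2931 ± 1345 (0.0882). Tcf7 stood at 1030.4 ± 220.3 and 519.7 ± 42.8 (0.12). Cxcr5, a receptor for follicular homing, was at 306 ± 0.669 and 24.1 ± 33.1 (0.112), and Ncr1, the NKp46 receptor, at 15.1 ± 10 and 99.2 ± 26.6 (0.127).

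**Figure D2:**
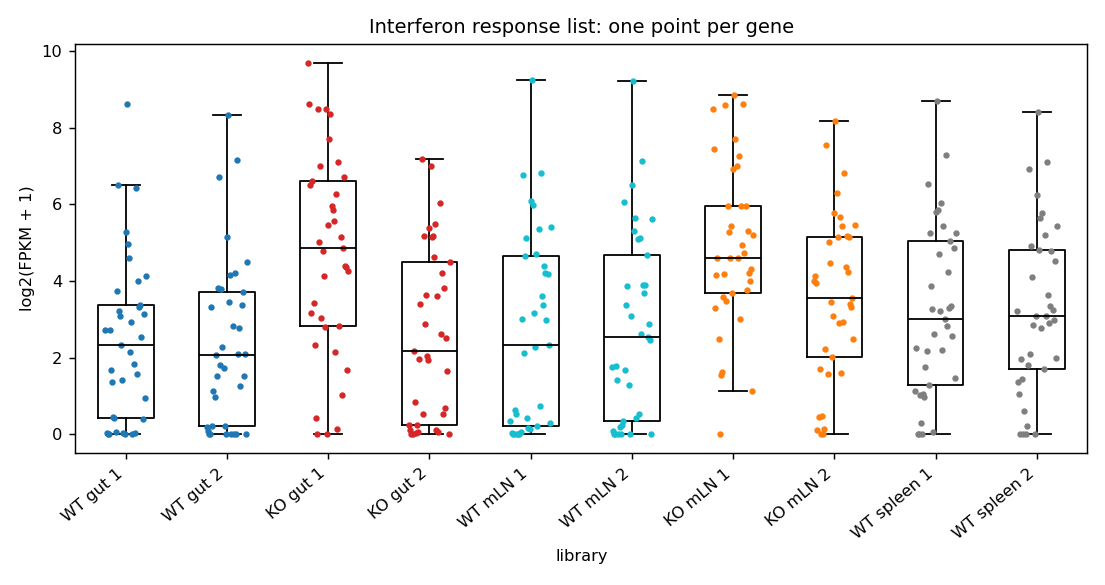
Levels of 37 interferon response genes as log2(FPKM + 1) on the vertical axis in each of the 10 libraries (horizontal axis), with 1 point per gene, a box for the median and quartiles, and whiskers to the farthest genes not counted as outliers. The medians were 4.87 in KO gut 1 and 4.6 in KO mLN 1, 3.55 in KO mLN 2, 2.18 in KO gut 2 and between 2.08 and 3.08 in the WT libraries.

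The mLN comparison gave 59 genes higher and 49 lower in KO (limma, adjusted p under 0.05). Its 108 calls became 56 without WT gut 1, 57 without WT gut 2, 16 without WT mLN 1, 239 without WT mLN 2, 12 without KO mLN 1, 28 without KO mLN 2, 36 without WT spleen 1 and 35 without WT spleen 2. The count was 63 with voom, 14 without both KO libraries numbered 1, and 0 without the 2 libraries richest in Gm23935. Of the 26 named genes past the threshold, Trdj1, Trdj2, Id3, Fads2 and Ccr8 stayed past it without any 1 library. The other 21 lost it without at least 1, with adjusted p up to 0.202 without KO mLN 1 and 0.211 without WT mLN 1. Of 26 alternatives the call of Ighd held in 7 and that of Trdd2 in 10, and of 27 that of Cd27 in 13 (0.0647 with voom) and that of Cd28 in 17. Of the 26, voom kept 9, median-of-ratios scaling 24 and quantile normalization 26. List calls in mLN held in 28 of 29 alternatives for T cell genes, 27 for interferon response and for B and plasma cell genes, 25 for ribosomal proteins and 18 for E protein driven genes.

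Genes changed in both tissues were then counted. Both comparisons had 14 genes higher, where independent lists would share 0.25, and 9 lower, where they would share 0.211. The comparisons use the same estimate of each gene's spread, so their calls are not independent and part of the excess may come from that. The shared increases were 5830411N06Rik, Cbfa2t3, Cd28, Clec12a, Dok3, Fads2, Id3, Ly6a, Nsg2, Olfr523, Sult5a1, Tasp1, Trdj1 and Trdj2, and the shared decreases Apol7b, Arhgef28, Ccr8, Cntn1, Cx3cl1, Hmgn3, Id2, Kcnk1 and Psd2. Only the predicted gene Gm13840 passed in opposite directions, named here after its values were seen: it was higher in KO gut (log2 change 4.51) and lower in KO mLN (-4.34). Of the 111 genes called in gut 74 had the same sign in mLN (66.7%), as did 74 of the 108 called in mLN (68.5%). Across all genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.18 and a Spearman correlation of 0.1. The Pearson value was 0.14 without KO gut 1, 0.21 without WT mLN 1 and 0.11 without WT mLN 2.

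**Figure D3:**
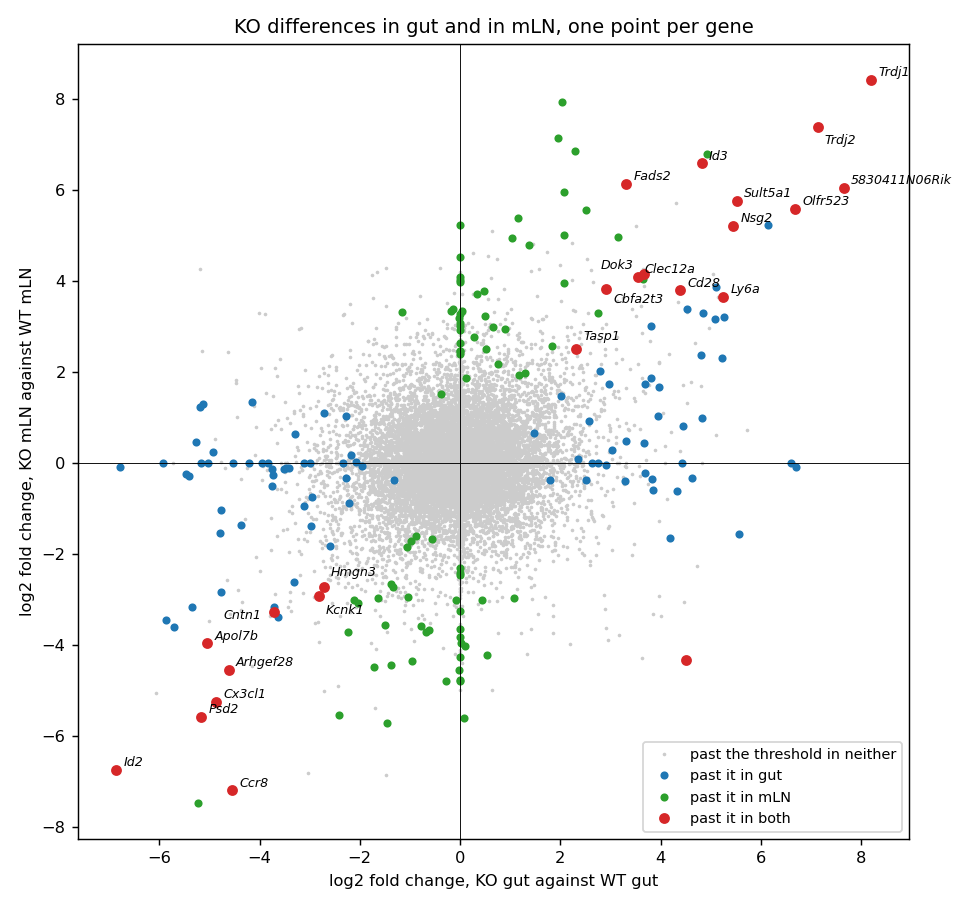
Log2 fold change of KO over WT in gut (horizontal axis) and in mLN (vertical axis), with 1 point per gene and colours for genes past the threshold in neither, 1 or both tissues. The 14 shared increases lie at upper right, led by Trdj1 at 8.2 and 8.41, the 9 shared decreases at lower left, with Id2 at -6.86 and -6.75, and the unnamed point past the threshold in both at lower right is Gm13840.

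A test of whether the KO change differed between gut and mLN found no gene (limma interaction, 0 past adjusted p 0.05, smallest 0.0852). At an unadjusted p under 0.05 there were 1262 genes where 649 would be expected by chance, and voom called 1. The count was 28 without WT mLN 2. The genes with the smallest p were given by their values. Acod1 was at 165 ± 9.94 FPKM in KO gut, 0.732 ± 0.983 in WT gut and 0 in KO mLN (adjusted p = 0.0852). Styx and Cxcl1 had interaction log2 values of -5.72 and -6.69 at the same adjusted p. Il10, an anti-inflammatory cytokine, was at 20.7 ± 1.98 in KO gut and 0 in WT gut, at least 91.1-fold, with an interaction value of 4.43 (adjusted p = 0.1). Il17a had 6.61 (adjusted p = 0.121), being at 0 in both mLN groups.

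The WT groups were compared to ask how LTi-like cells differ between tissues. The log2 changes of all genes had a median of -0.31 for gut against mLN, and gene changes below are given relative to that median, while each p tests the change before the median is subtracted. Gut cells had far more Crem, a cAMP-responsive transcriptional modulator (541 ± 89 FPKM against 5.9 ± 4.87, relative log2 change 6.81, limma adjusted p = 0.00203), and Ramp3, a partner of the calcitonin-like receptor (2303 ± 184 against 12.1 ± 15.7, 8.67, adjusted p = 0.0105). Tnfsf11, the cytokine RANKL, was at 621 ± 2.38 in gut and 33.2 ± 21.3 in mLN (relative change 4.65), and Il22 at 18425 ± 929 and 2931 ± 1345 (3.04, adjusted p = 0.0374). The Il22 call held in 12 of 27 alternatives, with adjusted p from 0.00896 to 0.255 (0.182 with quantile normalization). In the opposite direction, Lta was at 62.4 ± 46.3 in gut and 578 ± 184 in mLN (relative change -3.06), and Ltb, the other lymphotoxin subunit, at 333 ± 45.2 and 959 ± 107 (-1.21).

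Gut cells also had more Cxcl1 (139.8 ± 103 against 0.0757 ± 0.107 FPKM), the endosomal regulator Litaf (411 ± 78.6 against 6.86 ± 3.39), and the glycolytic enzyme Hk2 (95.8 ± 24.6 against 2.27 ± 1.46). The same held for Il17f (184 ± 166 against 3.11 ± 3.11, where voom gave an adjusted p of 0.404), and Fasl (34.9 ± 3.16 against 0, at least 192-fold). The cells in mLN had more of the retinoic acid receptor Rarg (87.7 ± 21.8 against 0.0364 ± 0.0181, relative change -6.08), and of the membrane protein genes Ms4a4c (179.9 ± 133 against 0.489 ± 0.534) and Emp3 (118 ± 28.9 against 2.2 ± 1.57). Also higher there were Tnfsf14, which encodes the cytokine LIGHT (57.6 ± 20.4 against 2.07 ± 2.85), the sphingosine phosphate receptor S1pr4 (96.7 ± 46.5 against 2.43 ± 1.16) and Ly6a (35.4 ± 13.8 against 0.542 ± 0.539). Crem, Litaf, Hk2, Ramp3 and Piwil4 overlap a gene on the other strand, and the counting's use of strand is not given in the sources used here.

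Of 23 NF-kappaB and TNF response genes 7 rose in gut over mLN, none fell and 16 did not pass. Adjusted over the list alone 11 rose (median relative to all genes 1.69, camera adjusted p = 9.34e-12, adjusted p = 0.0867 with an estimated correlation). Rel, an NF-kappaB subunit, was at 78.9 ± 3.5 FPKM in gut and 4.68 ± 2.32 in mLN. The inhibitors Nfkbid and Nfkbie stood at 338 ± 7.79 and 787 ± 0.156 against 61.1 ± 25.2 and 229 ± 3.16, and Cd83, an activation marker, at 297 ± 179 against 43.5 ± 10.8. Of 16 myeloid genes Lyz2, a lysozyme of macrophages (93.1 ± 26.8 against 0.858 ± 0.311), and the complement gene C1qb (23 ± 3.79 against 0.173 ± 0.124) rose and 14 did not pass. Adjusted over the list alone 6 rose and 2 fell (median 0.94, camera adjusted p = 0.00867, adjusted p = 0.38 with an estimated correlation). The myeloid call was lost without WT mLN 1 (0.0569).

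Of 22 LTi and ILC3 identity genes 4 rose in gut (Tnfsf11, Rora, Kit and Gpr183), 3 fell (Lta, Ltb and Ccr6) and 15 did not pass, with 7 and 5 adjusted over the list alone. Rora, an orphan nuclear receptor, was at 148 ± 2.07 FPKM against 28.4 ± 17, and Ccr6, a receptor for CCL20, at 142 ± 19.3 against 383 ± 68.9. Of 27 alternatives Ccr6 passed in 9 (adjusted p up to 0.199, 0.108 with median-of-ratios scaling), Rora in 14, Kit in 15, Ltb in 18, Lta in 20 and Tnfsf11 in 25. This list's camera adjusted p was 0.0273 (median 0.61), and adjusted p = 0.38 with an estimated correlation. The call was lost without WT gut 1 (0.0804), without WT gut 2 (0.0684), and under quantile normalization (0.0881). Of 14 MHC class II genes the invariant chain Cd74 fell in gut (41.1 ± 0.385 against 545 ± 68.8) and 13 did not pass, and 8 fell adjusted over the list alone (median -1.3, camera adjusted p = 0.00456, adjusted p = 0.38 with an estimated correlation, 0.145 without WT mLN 2). Circadian clock genes (3 risen of 18, among them Nfil3 at 533 ± 80.1 against 116 ± 17.5, and 4 adjusted over the list alone) had a median of 0.44 and a camera adjusted p of 0.00456 (adjusted p = 0.277 with an estimated correlation).

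Of 27 immediate early genes 3 rose (Fosl2, Nr4a2 and Nr4a3), 2 fell (Ier2 and Zfp36) and 22 did not pass, with 7 and 2 adjusted over the list alone. Fosl2, an AP-1 subunit, was at 129.6 ± 22.3 FPKM in gut and 5.95 ± 1.7 in mLN. The list had a camera adjusted p of 0.00456 (median 0.82, adjusted p = 0.449 with an estimated correlation), lost without WT mLN 2 (0.0552) and under quantile normalization (0.0549). Of 33 lymphoid transcription factors Rora and Nfil3 rose, Sox4 fell and 30 did not pass, with 5 and 4 adjusted over the list alone (median 0.47, camera adjusted p = 0.0225, adjusted p = 0.277 with an estimated correlation). That call was lost without WT gut 1 (0.0748) or WT mLN 2 (0.145). Among 19 ILC1 and NK genes Fasl and the receptor Klrk1 (136 ± 48.1 against 27.1 ± 3.12) rose and 17 did not pass. With the list alone adjusted, 2 rose and 2 fell (median 0.83, camera adjusted p = 0.0435, adjusted p = 0.38 with an estimated correlation). It was lost without WT gut 2 (0.11), WT mLN 2 (0.28), KO mLN 1 (0.0916) or KO mLN 2 (0.0927), and with median-of-ratios scaling (0.104) or quantile normalization (0.147).

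Ribosomal protein genes had a median of -0.48 in gut relative to all genes, with Rps27 fallen (47 ± 8.9 FPKM against 138 ± 34.3), 84 of 85 not past and none past adjusted over the list alone (camera adjusted p = 3.69e-07, adjusted p = 0.449 with an estimated correlation). Their median log2 level was 5.43 in WT mLN 1, the library with the most Gm23935, against 4.63 in WT mLN 2 and 4.22 and 4.31 in WT gut. None of 46 nuclear genes of oxidative phosphorylation passed on either adjustment (median -0.36, camera adjusted p = 0.01, adjusted p = 0.449 with an estimated correlation). Their call was lost without WT gut 1 (0.0804) or WT mLN 1 (0.134), with median-of-ratios scaling (0.138) and with voom (0.134). The 6 erythroid genes, led by Hba-a1 at 424 ± 599 in gut from WT gut 1, had none past on either adjustment (median 3.55, camera adjusted p = 0.0124, adjusted p = 0.38 with an estimated correlation). Without WT gut 1 the erythroid value was 0.573, without WT mLN 1 0.101 and without WT mLN 2 0.0552.

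In total 218 genes were higher and 260 lower in WT gut than in WT mLN (limma, adjusted p under 0.05), so 45.6% of calls were higher. With median-of-ratios scaling the split was 312 and 160 (66.1% higher), and with quantile normalization 270 and 165 (62.1%). The 478 calls became 61 without WT gut 1, 132 without WT gut 2, 147 without WT mLN 1, 260 without KO mLN 1, 256 without KO mLN 2, 188 without WT spleen 1 and 191 without WT spleen 2. Of 55 named genes past the threshold Cxcl1, Crem, Litaf, Lyz2, Ms4a4c, Rarg, Emp3, Piwil4, Fasl, Ly6a and Hk2 stayed past it without any 1 library. The other 44 lost it without at least 1, 40 of them without WT gut 1 (adjusted p up to 0.242). Calls held in 8 of 27 alternatives for Zfp36 and Sox4, 9 for Nr4a2 and Rps27, 11 for Cd83 (0.0772 with voom), 15 for S1pr4, 16 for Cd74 and 17 for Nfil3. Voom kept 39 of the 55, median-of-ratios scaling 48 and quantile normalization 47. Among the list calls NF-kappaB held in 28 of 29 alternatives, circadian clock and ribosomal proteins in 27, and MHC class II, lymphoid transcription factors and myeloid genes in 26. Immediate early genes held in 25, LTi identity in 24, oxidative phosphorylation in 23, ILC1 and NK genes in 15, and the erythroid call in 22 of 28.

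Gut and spleen cells differed in many of these genes, with an all-gene median of -0.41 to which the following changes are relative. Pdcd1, the inhibitory receptor PD-1, was at 486 ± 0.774 FPKM in gut and 0.984 ± 1.19 in spleen (relative log2 change 8.49, adjusted p = 3e-04). Il22 was at 18425 ± 929 and 161 ± 21 (7.24, adjusted p = 0.000812), Il17f at 184 ± 166 and 0.442 ± 0.0537 (7.03), and Tnfsf11 at 621 ± 2.38 and 13.3 ± 3.33 (5.87). Crem (2.86 ± 2.05 in spleen), Litaf (4.2 ± 1.52), Hk2 (0.927 ± 0.172) and Socs3, an inhibitor of cytokine signalling (545 ± 34.2 in gut against 71.5 ± 29.3), were also higher in gut. Spleen cells had more Ms4a4c (377 ± 119, relative change -7.59), Rarg (78.7 ± 17.2), the gut homing receptor Gpr15 (119 ± 24.7 against 0.0784 ± 0.111 in gut) and the egress receptor S1pr1 (62.2 ± 2.78 against 6.65 ± 0.364). Other genes higher in spleen were Lta (674 ± 210.3), Ltb (739 ± 2.79) and Gata3, a transcription factor of lymphocytes (63.9 ± 0.704 against 16 ± 2.62).

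Of the 23 NF-kappaB genes 9 rose in gut over spleen, none fell and 14 did not pass, and adjusted over the list alone 13 rose and 1 fell (median 1.89, camera adjusted p = 7.87e-15, adjusted p = 0.0518 with an estimated correlation). They included Nfkbid (40 ± 5 FPKM in spleen), Rel (6.47 ± 4.46), Cd83 (39.2 ± 14.7) and the chemokine Cxcl2 (25.6 ± 17.3 in gut, 0 in spleen). Of 18 circadian genes 5 rose on either adjustment and 13 did not pass, among them Bhlhe40, a repressor of the clock (868 ± 53 against 161 ± 7.07), and Per1 (98 ± 38.3 against 6.63 ± 2.97). That list's median was 0.53 (camera adjusted p = 0.000204, adjusted p = 0.117 with an estimated correlation). Among 33 lymphoid transcription factors Rora and Nfil3 rose, Gata3 fell and 30 did not pass, with 5 and 1 adjusted over the list alone (median 0.87, camera adjusted p = 0.000496, adjusted p = 0.0743 with an estimated correlation).

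The LTi identity genes that passed against spleen were the 7 that passed against mLN, 4 higher and 3 lower with 15 not past. Adjusted over the list alone, 5 rose and 3 fell (median 0.64, camera adjusted p = 0.00783, adjusted p = 0.307 with an estimated correlation, 0.0737 under quantile normalization). Lyz2 (8.39 ± 2.67 FPKM in spleen) and C1qb again rose among 16 myeloid genes and 14 did not pass. When adjusted over the list alone, 6 rose and 2 fell (median 1.06, camera adjusted p = 0.00783, adjusted p = 0.535 with an estimated correlation, 0.0632 under quantile normalization). Cd74 fell among 14 MHC class II genes (402 ± 2.79 in spleen), with 4 fallen adjusted over the list alone (median -1.4, camera adjusted p = 0.00783, adjusted p = 0.535 with an estimated correlation). The 6 erythroid genes had a median of 3.37 with none past on either adjustment (camera adjusted p = 0.0114, adjusted p = 0.535 with an estimated correlation, 0.971 without WT gut 1 and 0.101 without WT spleen 1).

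The gut and spleen comparison called 210 genes higher and 246 lower in gut (limma, adjusted p under 0.05, 46.1% higher), against 307 and 173 with median-of-ratios scaling (64%) and 322 and 205 with quantile normalization (61.1%). The 456 calls became 137 without WT gut 1, 190 without WT gut 2, 71 without WT spleen 1 and 59 without WT spleen 2. Of 60 named genes past the threshold Pdcd1, Crem, Cxcl1, Il22, Litaf, Ms4a4c, Rarg, Emp3, Tnfsf11, Fasl, Socs3, Fosl2 and Hk2 stayed past it without any 1 library. The other 47 lost it without at least 1, with adjusted p up to 0.265 without WT spleen 1. Over 27 alternatives the call of Cd74 held in 14, Ltb in 15 (0.149 with median-of-ratios scaling), Cd83 in 16, Kit in 17, Ccr6 in 19, Per1 in 20, Gata3 in 21, Lta and Gpr183 in 22, Rora in 23 and Tnfsf11 in 26. With voom 50 of the 60 passed, with median-of-ratios scaling 55 and with quantile normalization 57. The calls of NF-kappaB, circadian clock and lymphoid transcription factor genes held in 28 of 29 alternatives, LTi identity and MHC class II in 27, myeloid genes in 25, and the erythroid call in 20 of 28. The gut comparisons with mLN and with spleen share the WT gut libraries. They had 152 higher and 149 lower calls in common, where independent lists would share 3.53 and 4.93. Their log2 changes correlated at 0.74 against 0.5 in 20 simulations of unchanged groups, with a covariance of 1.2 against 0.32, a difference of 0.88, and part of the excess in shared calls may come from the shared libraries.

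No gene passed between WT mLN and WT spleen (limma, 0 at adjusted p 0.05, smallest 0.079), with 807 genes at an unadjusted p under 0.05, 649 expected by chance, and 0 by voom. The count was 76 without WT mLN 2, 2 without KO mLN 1 and 2 without KO mLN 2. The genes with the smallest p included Pdcd1 (24.8 ± 7.45 FPKM in mLN, 0.984 ± 1.19 in spleen, adjusted p = 0.081) and Il22 (2931 ± 1345 and 161 ± 21, 0.163). Next came the stress gene Gadd45b (224 ± 7.69 and 52.1 ± 24.3, 0.215) and the galectin Lgals1 (12.6 ± 3.57 and 109.5 ± 14.1, 0.254). Il7r was at 687 ± 48.6 and 687 ± 34.3, Rorc at 57.9 ± 16 and 58.7 ± 12.4, and Tcf7 at 519.7 ± 42.8 and 444 ± 19.9.

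None of the members of the 3 lists past the camera threshold between mLN and spleen passed on either adjustment. Of 85 ribosomal protein genes 81 were above 0 in mLN (median 0.5, camera adjusted p = 2.05e-09, adjusted p = 0.495 with an estimated correlation), lost without WT mLN 1 (0.142), which also had the most Gm23935. The 20 proliferation genes had a median of -1.07 (camera adjusted p = 0.00019, adjusted p = 0.433 with an estimated correlation), lost without WT spleen 1 (0.114). The 19 ILC1 and NK genes had a median of -0.56 (camera adjusted p = 0.0403, adjusted p = 0.433 with an estimated correlation), lost without WT mLN 2 (0.365) or WT spleen 2 (0.118). Of 29 alternatives the proliferation call held in 26, that of ribosomal proteins in 25 and that of ILC1 and NK genes in 21. Mcm2, a replication licensing factor, was at 5.83 ± 2.13 in mLN and 25.9 ± 8.36 in spleen.

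The tissue difference was also measured between KO gut and KO mLN, with an all-gene median of -0.35. Il17f was at 2395 ± 1202 FPKM in KO gut and 16.1 ± 9.12 in KO mLN (relative log2 change 7.5, limma adjusted p = 0.00469), Il17a at 151 ± 154 and 0 (adjusted p = 0.00555). Il22 was at 5115 ± 813 and 578 ± 487 (3.8, adjusted p = 0.0188) and Tnfsf11 at 595 ± 157 and 56.8 ± 21.3 (3.74). Acod1 (165 ± 9.94 against 0), Crem (506 ± 149 against 7.82 ± 1.69), Litaf (449.6 ± 174 against 7.91 ± 5.04), Lyz2 (121 ± 62.4 against 0.684 ± 0.0258) and Car2 (81.8 ± 8.69 against 2.45 ± 3.14) were higher in KO gut. Styx (0.404 ± 0.316 against 61.8 ± 17.2), Rarg (0.136 ± 0.0254 against 33.6 ± 2.94), Ltb (258 ± 63.2 against 837 ± 53.9), Ly6a (61.4 ± 35.9 against 439 ± 9.42) and the plasma cell marker Sdc1 (9.68 ± 9.34 against 106 ± 46.8) were lower.

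Of 14 ILC3 cytokines and effectors Il22, Il17a, Il17f and Tnfsf11 rose in KO gut over KO mLN, Ltb fell and 9 did not pass. Over the list alone 6 rose and 1 fell (median 1.73, camera adjusted p = 0.000375, adjusted p = 0.0863 with an estimated correlation). NF-kappaB genes again rose, 7 of 23, with 16 not past and 11 adjusted over the list alone (median 1.55, camera adjusted p = 5.32e-09, adjusted p = 0.0863 with an estimated correlation). Cd83 was at 194 ± 98.2 FPKM against 5.53 ± 1.77 and Cxcl2 at 89 ± 41.5 against 0.0447 ± 0.0632. Lyz2 and C1qb rose among 16 myeloid genes and 3 adjusted over the list alone (median 1.47, camera adjusted p = 0.00101, adjusted p = 0.249 with an estimated correlation). Of 33 lymphoid transcription factors Rora rose, Gata3 fell and 31 did not pass, with 4 and 1 adjusted over the list alone (median 0.93, camera adjusted p = 0.0023, adjusted p = 0.0863 with an estimated correlation).

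The clock genes Nr1d2 and Rora rose among 18, with 4 adjusted over the list alone (median 0.92, camera adjusted p = 0.00167, adjusted p = 0.163 with an estimated correlation, 0.0615 without KO gut 1). Of 22 LTi identity genes Rora and Tnfsf11 rose and Ltb fell, with 3 and 1 adjusted over the list alone (median 0.64, camera adjusted p = 0.00374, adjusted p = 0.207 with an estimated correlation, 0.094 without KO gut 1, 0.108 under quantile normalization). Of 21 homing genes the chemokine receptor Cxcr4 rose (63.9 ± 1.37 FPKM against 15.4 ± 5.8) and S1pr4 fell (5.6 ± 7.41 against 83.9 ± 11.9), with 3 and 2 adjusted over the list alone. Their median before centring was 0.45 and their mean -0.03 (camera adjusted p = 0.024, upward, adjusted p = 0.281 with an estimated correlation, 0.118 without KO gut 1, 0.261 under quantile normalization). Hk2 and the hypoxia factor Hif1a rose among 21 glycolysis genes on either adjustment (median 0.69, camera adjusted p = 0.0253, adjusted p = 0.252 with an estimated correlation, 0.0919 without KO gut 1, 0.122 without KO mLN 1, 0.0766 under quantile normalization).

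**Figure D4:**
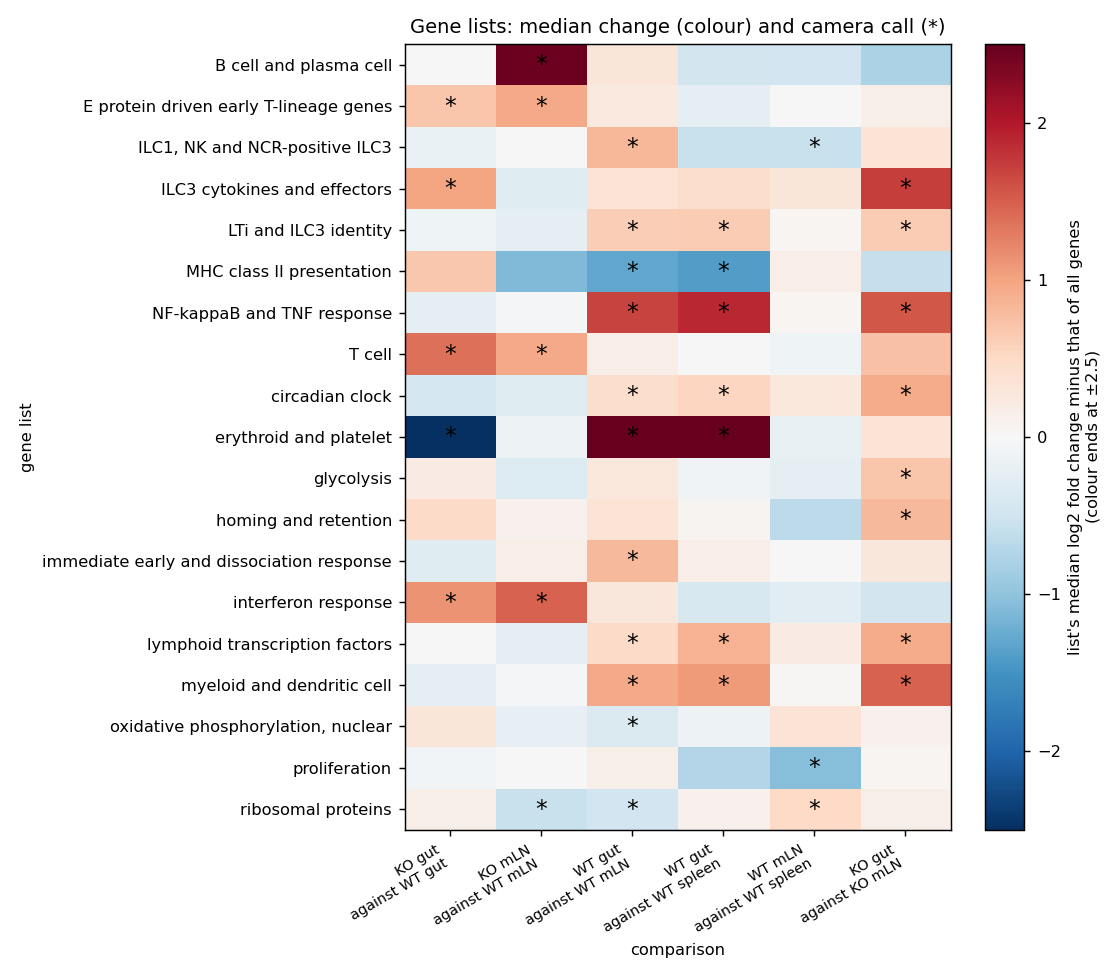
Median log2 change of each gene list minus that of all genes (colour, ending at ±2.5) for 6 comparisons on the horizontal axis, with a star where the camera adjusted p with the preset correlation was under 0.05. NF-kappaB and TNF response genes stood at 1.69, 1.89 and 1.55 in the 3 comparisons of gut with another tissue, and T cell genes at 1.37 and 0.94 in KO over WT.

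KO gut had 194 genes higher and 235 lower than KO mLN (limma, adjusted p under 0.05, 45.2% higher), against 280 and 163 with median-of-ratios scaling (63.2%) and 202 and 116 with quantile normalization (63.5%). The 429 calls became 254 without WT gut 1, 251 without WT gut 2, 270 without KO gut 2, 87 without KO mLN 1, 84 without KO mLN 2, 153 without WT spleen 1 and 145 without WT spleen 2. Without both KO libraries numbered 1 the fit called 0. Of 51 named genes past the threshold Acod1, Cxcl2, Lyz2, Osgin2, Crem, Litaf, Styx, Ighj3, Actr6, Rarg, Car2, Fosl2 and Cd83 stayed past it without any 1 library. The other 38 lost it without at least 1, with adjusted p up to 0.219 without KO mLN 1. Cxcr4 held its call in 9 of 27 alternatives, Gata3 in 12, Hif1a and S1pr4 in 14, and Sdc1 in 16. Of these 51, voom kept 39, median-of-ratios scaling 47 and quantile normalization 40. ILC3 cytokines, NF-kappaB and lymphoid transcription factors held their list calls in 28 of 29 alternatives, myeloid genes in 27, circadian clock in 26, LTi identity in 24, homing and retention in 23 and glycolysis in 22. The WT and KO tissue differences share no libraries but use the same estimate of each gene's spread. They had 93 higher and 41 lower calls in common where independent lists would share 3.26 and 4.71, and Gm13840 alone passed in opposite directions. Of the 478 WT calls 395 had the same sign in KO cells (82.6%), and across genes the Pearson correlation was 0.35 and the Spearman correlation 0.3.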

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

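The 4 results here come from planned tests of whether the KO change differed between gut and mLN, the interaction of genotype and tissue. The values with voom, with protein-coding genes only and without the 2 libraries richest in Gm23935 come from tests chosen after the results were seen.

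ILC3 cytokines and effectors moved upward in gut relative to mLN (median relative to all genes 1.4, camera adjusted p = 0.00325, adjusted p = 0.299 with an estimated correlation). Of 14 members 0 passed over all genes and 4 rose adjusted over the list alone. Without WT mLN 2 the value was 0.0526, and it stayed under 0.05 in the other 27 of 29 alternatives. The list B cell and plasma cell moved the other way (median -1.04, adjusted p = 0.0465, 0.436 with an estimated correlation). Of its 29 values under other settings or without 1 library 14 stayed under 0.05. The highest was 0.298, without WT gut 2, apart from the estimated correlation, and fry gave 0.0559.

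Nuclear oxidative phosphorylation genes had a median of 0.42 (adjusted p = 0.0465, 0.849 with an estimated correlation). That call was lost in most other fits, among them those without KO gut 2 (0.484) or WT mLN 1 (0.313), with quantile normalization (0.168), voom (0.203) and fry (0.404). The ribosomal proteins had a median of 0.66 (adjusted p = 1.04e-06, 0.849 with an estimated correlation), and fry gave 0.404. Without the 2 libraries richest in Gm23935, WT mLN 1 and KO gut 2, the value of the ribosomal proteins was 0.409 and that of oxidative phosphorylation 0.771.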

How the results depend on the processing

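Voom, leaving out the 2 libraries richest in Gm23935 or both KO libraries numbered 1, and protein-coding genes only were tests chosen after the data were seen, and the others were planned. No named gene or list called at first was called in the opposite direction under any alternative run, but 75 of 562 named gene values, 0 of them called, changed sign in at least 1. The balance of calls turned with the scaling: 45.6% were higher in WT gut against WT mLN, 66.1% with median-of-ratios scaling and 62.1% with quantile normalization, and for WT gut against WT spleen 46.1%, 64% and 61.1%, and for KO gut against KO mLN 45.2%, 63.2% and 63.5%. Counts of changed genes moved most. For KO against WT gut (111 genes) they were 167 with median-of-ratios scaling, 66 with arrayWeights, 63 without the Gm23935-rich libraries and 30 without both KO libraries numbered 1. For KO against WT mLN (108) they were 63 with voom, 0 without the Gm23935-rich libraries and 14 without both KO libraries numbered 1. WT gut against WT mLN (478) had 250 with no filter, 309 without a trend, 261 with arrayWeights, 35 without the Gm23935-rich libraries and 254 without both KO libraries numbered 1. WT gut against WT spleen (456) had 1324 with arrayWeights. KO gut against KO mLN (429) had 243 with no filter, 252 with arrayWeights, 281 without the Gm23935-rich libraries and 0 without both KO libraries numbered 1. WT mLN against WT spleen (0) had 1 with a pseudocount of 5, 52 with no filter, 2 with quantile normalization and 1 without a trend, and the interaction (0) had 4 and 1 with pseudocounts of 0.1 and 5, 5 with rescaled columns and 1 with voom. Using only the libraries of the groups compared gave 0 in every comparison, with fewer residual degrees of freedom by construction. Id2 in gut was then -6.86 (adjusted p = 0.319) and in mLN -6.75 (0.33), neither under 0.05. Its adjusted p was also above 0.05 with voom in gut (-7.9, 0.0508) and without the Gm23935-rich libraries in mLN (-6.72, 0.0667). Of the 43 list calls 1 held with an estimated correlation. Fry made 23 calls, 17 of them among the 43. The correlation of KO changes between tissues (0.18) was 0.22 with a pseudocount of 5, 0.13 without both KO libraries numbered 1 and 0.21 with protein-coding genes only. Apart from the fits with fewer libraries, the cause was not tested.

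Leaving out each of the 10 libraries in turn gave 41 to 152 genes for KO against WT gut, 12 to 239 for KO against WT mLN, 61 to 555 for WT gut against WT mLN, 59 to 578 for WT gut against WT spleen, 0 to 76 for WT mLN against WT spleen, 0 to 28 for the interaction and 84 to 506 for KO gut against KO mLN. Id2 ranged from -8.22 to -5.51 in gut and from -7.42 to -6.08 in mLN, the list calls from 35 to 47 and the correlation from 0.11 to 0.21. A group left with 1 library was assumed to vary like the others. Of 219 named gene calls 54 were kept without any 1 library, 155 with voom, 201 with median-of-ratios scaling, 201 with rescaled columns and 195 with quantile normalization. With the replicate number as a block the counts were 75, 75, 316 (WT gut against WT mLN), 366, 0, 0 and 281 (KO gut against KO mLN), in the order KO gut, KO mLN, the 3 WT comparisons, the interaction and the KO tissue comparison, and 183 named calls were kept. Across all genes no pairing by number was seen: deviations of same-numbered libraries correlated at -0.03 to 0.04 over 10 pairs of groups. An all-gene correlation cannot exclude that same-numbered libraries share an animal or a day. Among results for single lists and named genes, 58 list values and 772 gene values lost their call when 1 library was left out, 32 and 41 gained one, and 1730 and 4807 kept their side of the threshold. Under the other settings 140 list values and 813 gene values lost a call, 50 and 52 gained one, and 3261 and 8632 kept theirs. With 2 libraries per group, changes under about 4-fold were mostly not detectable, as 32.5% of simulated 4-fold changes were recovered in KO against WT gut.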

Other observations

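All explanations weighed here were tested after the results were seen, and several bounds were changed with the values known. For T cells the bound of 50% of Trdc was set so, and excluded them in mLN. A comparison with CD3 in the WT libraries of all tissues was added, with the same outcome, and then limited to the same tissue, which left T cells open. For the interferon list in KO library 2 the bound was first 0.2 above WT, which excluded the genotype in gut, then 0, which left it open. It was then 2 standard errors from WT and 1 SD below library 1, which excluded it again, and last standard errors that allow for the correlation between members, which leave it open. The macrophage test first used 8 transcripts, then 4, and called macrophages excluded by a ratio of 0.5 that no table measures, and that reading was dropped. A tissue difference in both genotypes was first read as supported by a count that the other explanations predict as well.

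Reads on T cell receptor delta segments were found in the KO libraries, with the strand untested, since predicted genes overlap these segments on the other strand. Trdc, the delta constant region, was at 7.34 and 17.99 FPKM in KO gut and at 9.22 and 25.27 in KO mLN, against at most 0.16 in any WT library. Reads on Trdj1 and Trdj2 together numbered 227 and 187 in KO gut and 181 and 449 in KO mLN, while alpha and delta variable segments had 30 and 11 reads in KO gut and 0 and 3 in KO mLN.

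For Trdj1 and Trdj2, a few reads inflated by the short segments are argued against by the 181 reads in the lowest KO library and 0 in the WT libraries. For Trdd2, with 18 and 21 reads in KO mLN and 0 and 3 in KO gut, this was not tested. T cells in the sorts stay open in both tissues, as how much CD3 or variable-segment RNA such cells would bring was not measured. In KO mLN the summed FPKM of Cd3d, Cd3e and Cd3g was 1.07 and 1.05, or 11.6% and 4.14% of Trdc, against 0 and 0.51 in WT mLN and 1.15 in the highest WT library, from spleen. Cd3e was at 0 in both KO mLN libraries, and Trac at 9.89 and 6.33 FPKM against 0.46 and 10.88 in WT mLN. Adjusted over the list alone, 7 of 16 T cell genes rose in KO mLN (median 0.94, camera adjusted p = 9.53e-06, 0.0881 with an estimated correlation). In KO gut the CD3 sum was 4.2 and 3.67 FPKM, 57.2% and 20.4% of Trdc, and Trac stood at 54.28 and 82.3. KO gut 2 also held the T cell list genes Cd8b1 (13.5 FPKM), Cd40lg (16.99) and Cd247 (6.1), which were at 0, 0.59 and 0 in KO gut 1. It had the higher Il17a as well (259.65 against 41.99 in KO gut 1). The sort took lineage-negative cells, but the antibodies of that panel are not given in the sources used here. Release of E protein activity without Id2 is a candidate explanation that also stays open. The list of E protein driven early T-lineage genes had a median above 0 in both tissues, but its higher adjusted p with an estimated correlation was 0.315.

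Interferon response genes were high in both KO libraries numbered 1. In KO gut 2 the list stood 0.13 above the WT mean, against 1.58 in KO gut 1, and the call ended without KO gut 1 (0.621). That contrast between the libraries is the pattern itself, and the standard error of the value in KO gut 2 was 0.8 with the estimated correlation of 0.35 between members. That correlation was estimated from differences between libraries of the same group, which hold this same gap. Standard errors built on it, here and in mLN, therefore cannot decide. The genotype in every KO gut library therefore stays open. In KO mLN 2 the list stood 0.65 above WT, with a standard error of 0.72 (1.95 in KO mLN 1). Its adjusted p was 0.00277 without both KO libraries numbered 1, and 0.548 with an estimated correlation over all libraries, so the genotype in mLN stays open. An exposure shared by the KO gut and KO mLN libraries numbered 1 stays open too. Of 37 members 27 (73%) were higher in library 1 in both KO groups, against 20.9% of all genes, but that count restates the pattern and supports nothing. Nothing in the labels ties these libraries to each other, and the difference between libraries 1 and 2 correlated at 0.04 across all genes.

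Of 23 NF-kappaB genes 7 rose in gut over mLN and 9 over spleen, and the list calls were lost with an estimated correlation (0.0867 and 0.0518). A tissue difference present in both genotypes stays open. Of the 7 members that rose in WT gut over WT mLN, 6 also rose in KO gut over KO mLN, adjusted over the list alone, but macrophages or dissociation would give the same, and 82.6% of all WT calls had the same sign in KO cells. Macrophages in the gut sorts stay open, although the gate (lineage-negative, CD90, CD127, CD4 and Rorc positive) should remove them. Lyz2, C1qa, C1qb and C1qc gained a median of 42.3 FPKM from spleen to gut. The 9 NF-kappaB members that rose, picked for rising, gained a median of 253.4. Cd68 was at 10.78 and 6.86 in WT gut, at 4.63 and 8.24 in WT mLN and at 0.98 and 0.36 in spleen, while Csf1r and Adgre1 were at 0 in both WT gut libraries. How much NF-kappaB RNA such cells would bring was not measured. A response to tissue dissociation stays open as well. The immediate early list had a median of 0.16 between gut and spleen with an SD of 2.1 over members (camera adjusted p = 0.0502). Of its members 7 rose and 3 fell adjusted over the list alone, which does not decide. Between gut and mLN its median was 0.82 (adjusted p = 0.00456, 0.449 with an estimated correlation), with 7 members risen and 2 fallen adjusted over the list alone, which goes with dissociation. Between KO gut and KO mLN, where NF-kappaB genes had a median of 1.55, the immediate early list had a median of 0.29 (camera adjusted p = 0.075). With 8 risen and 6 fallen, that does not decide either. Tissue and dissociation differ between the same groups.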
